A study of Homo sapiens with 22 samples.

How the data were processed

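Per the labels' protocols, RNA was extracted from transfected cells, polyadenylated RNA was selected and copied into cDNA, and a short stretch holding the 12-base tag of each reporter was amplified for sequencing. The plasmid pool was amplified from DNA in the same way as an input library, 1 for each cell line. No molecular identifiers are described, so reads of a tag are not independent molecules, and intervals on shares cover counting error only. The submitters' processing notes name bcl2fastq, without a version. How reads were matched to tags, and which tags were kept, is not given in the sources used here.

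Per the file headers, each deposited file lists tags with a raw read count, the library's total count, and a TPM value. The deposited counts of a library add up exactly to its total, and the TPM (tags per M of counts) values equal the count divided by that total, as recomputed from every file. A file lists a tag only if it was read at least once. A deposited tag has 15 bases, of which 12 vary and the last 3 are the same in all tags. Tags are synthetic and have no position in a genome, so no build or annotation applies.

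Counts of the 22 libraries were joined on the tag, with 0 for a tag that a library did not list. A tag entered a test if it had at least 10 counts in the input of the line concerned, or in both inputs where both lines were compared. Activity was log2 of RNA TPM plus a pseudocount of 0.5 over input TPM plus 0.5, minus the median of that library, so a value of 0 is the typical tag. The design fixed before the data were examined called for sums over the tags of each cloned fragment and for tests between alleles. No table pairing tags with fragments, alleles, orientations or control fragments was used here. The unit of every test therefore became the tag, and the allelic, allele by BaP, orientation, scrambled-control, motif and index-variant comparisons were not analysed here. Several tags can mark the same fragment, so counts of tags are not counts of regulatory fragments, and tags are not independent of each other.

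Activity was tested in each group with limma's treat against a 2-fold change from the library median, the fallback written for the case without control fragments. BaP was compared with DMSO within each line by edgeR's quasi-likelihood test with TMM normalization, filterByExpr and robust dispersions, on the 10 RNA libraries of that line. The difference of the BaP responses was the line by treatment interaction in the same kind of fit over 20 libraries. A549 was compared with H520 in DMSO with edgeR's glmTreat at 2-fold, with the log input TPM of each line as an offset. That last comparison was added after the files were seen. All adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05. A p-value measures the spread between transfections, which the labels do not tie to separate cell cultures.

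Tags were also sorted into classes by their mean activity over the 10 RNA libraries of each line, by limits chosen after the data were seen. A class needed a log2 activity of at least 1. Tags within 1 log2 unit of each other in both lines were called balanced, and those that differed by 1 or more were called A549-biased or H520-biased. Tags at 4 or more in A549 and under 0.5 in H520 were called A549-restricted. The mean level of a class in each library was compared between 5 DMSO and 5 BaP transfections with a two-sided exact permutation test, whose smallest possible p is 0.0079. BaP calls were also adjusted over the active tags alone, which is the 3167 tags in any class.

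The rule for named items could not be used as written, since it needs both alleles of a variant. In its place, the text names the 5 tags with the highest DMSO activity in each line and the 3 with the largest line difference each way, among calls with at least 500 counts in both inputs. It also names the tag with the smallest p in each BaP test and the BaP calls among active tags. This rule was chosen after values had been seen.

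Libraries held 177.6 to 371.4 M counts (M, mega), and the median listed tag had 549 to 1214 counts. Pairs of libraries of a group had Pearson r of log2 TPM across tags of 0.976 to 0.995, and all pairs differed by more than sampling noise, with chi-square values of 3.82 to 94.33 per degree of freedom. No library was a copy of another.

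The tests were tried on simulated counts with the real tags, library sizes and dispersions. Over 223066 tags in A549, 35.5% of 200 tags changed 1.25-fold, 79.5% of those changed 1.5-fold and 94.5% of those changed 2-fold were called, and 6.5% of calls were unchanged tags. Over 223732 tags in H520 these shares were 55.0%, 90.5% and 96.5%, with 4.5% unchanged. The changed tags were drawn at random from all tested tags, most of them in no activity class, with errors independent between tags. These shares therefore do not give the power for active tags. The mean log2 level of A549-biased tags alone had an SD between A549 transfections of 0.40 with DMSO and 0.53 with BaP (n = 5 each). The activity test called 86.3% of 300 tags set at 4-fold and 0 unchanged tags. The line comparison called 99.0% of 300 tags set 6-fold apart, and 0 of the unchanged ones. In that simulation both inputs were drawn from 1 common pool with counting noise alone. The real inputs differed more. In tags of no class with at least 100 counts in both inputs, the log2 input ratio had an SD of 0.38, where the counting error of A549-restricted tags was 0.05. The 0 therefore does not carry over to the real line calls.

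Alternatives included RLE size factors, library totals, no expression filter, other input minimums of 1 and 50, pseudocounts of 0.1 and 1, a threshold of 0.01, DESeq2, one fit over all RNA groups, the transfection number as a block, and leaving out each library. Alternatives added after seeing the data were activity without centring, the input of the other line or the mean of both inputs as the denominator, removal of tag GC content, and the line comparison without the input offset. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.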

Results

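The series measured transcription from a pool of luciferase reporter plasmids, each marked by a sequence tag in its transcript. The pool was transfected into A549 cells, a human lung adenocarcinoma line, and into H520 cells, a human lung squamous cell carcinoma line. Its title places it in the search for variants that act on lung cancer susceptibility. Cells received vehicle (DMSO) or 10 µM benzo(a)pyrene (BaP), a polycyclic aromatic hydrocarbon of tobacco smoke that activates the aryl hydrocarbon receptor. Exposure lasted 18 h in A549 and 42 h in H520. Each of the 4 combinations had 5 transfections, and each line had 1 library of input DNA, for 22 libraries in all.

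Totals were 204.6 to 349.9 M counts per library in A549 with DMSO, 177.6 to 308.3 M in A549 with BaP, 179.3 to 331.7 M in H520 with DMSO and 200.3 to 371.4 M in H520 with BaP. The A549 input held 333.5 M counts and the H520 input 265.8 M. The libraries listed 238017 tags, of which 223760 were found in every library. At least 10 input counts were present for 223690 tags in A549 and for 224276 tags in H520. Log2 TPM of both inputs correlated across tags with a Pearson r of 0.961. The 10 most abundant tags took 1.47% ± 0.578 (SD, n = 5) of counts in A549 with DMSO and 0.365% ± 0.038 (SD, n = 5) in H520 with DMSO.

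The first comparison asked which tags marked reporters that were transcribed above the level of the pool. Most tags sat near that level: 90% of tags in A549 with DMSO lay between log2 activities of -0.36 and 0.48. A small set was strongly active. In A549 with DMSO, 2179 tags (0.97%) were more than 2-fold above the library median and 0 were more than 2-fold below it. In H520 with DMSO, 1753 tags (0.78%) were above and 25 below. With BaP, the counts were 2189 above and 0 below in A549 and 1803 above and 27 below in H520, all by limma's treat at an adjusted p of 0.05. Beside the count of 0, 20 tags in A549 with DMSO passed an unadjusted p of 0.05 on the low side.

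Much of the active set was shared between the lines. Of 2175 active tags in A549 and 1751 in H520 that could be tested in both, 1153 were active in both, where independent lists of that size would share 17.1. Activity across all 222696 tags correlated between the lines with a Pearson r of 0.578 and a Spearman rho of 0.399. These are values across tags, which are not independent replicates.

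Sorted by class, 1042 tags were balanced, 1602 were A549-biased, 433 were H520-biased and 90 were A549-restricted. Balanced tags had a mean log2 activity of 2.09 ± 0.06 (SD, n = 5) in A549 with DMSO and 2.33 ± 0.06 (SD, n = 5) in H520 with DMSO. The A549-biased tags stood at 2.06 ± 0.40 (SD, n = 5) in A549 and 0.51 ± 0.06 (SD, n = 5) in H520. The H520-biased tags stood at 0.89 ± 0.04 (SD, n = 5) in A549 and 2.16 ± 0.08 (SD, n = 5) in H520. The A549-restricted tags reached 4.54 ± 0.17 (SD, n = 5) in A549, which is 23.3 times the library median, and lay below the median in H520 at -0.34 ± 0.01 (SD, n = 5).

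**Figure D1:**
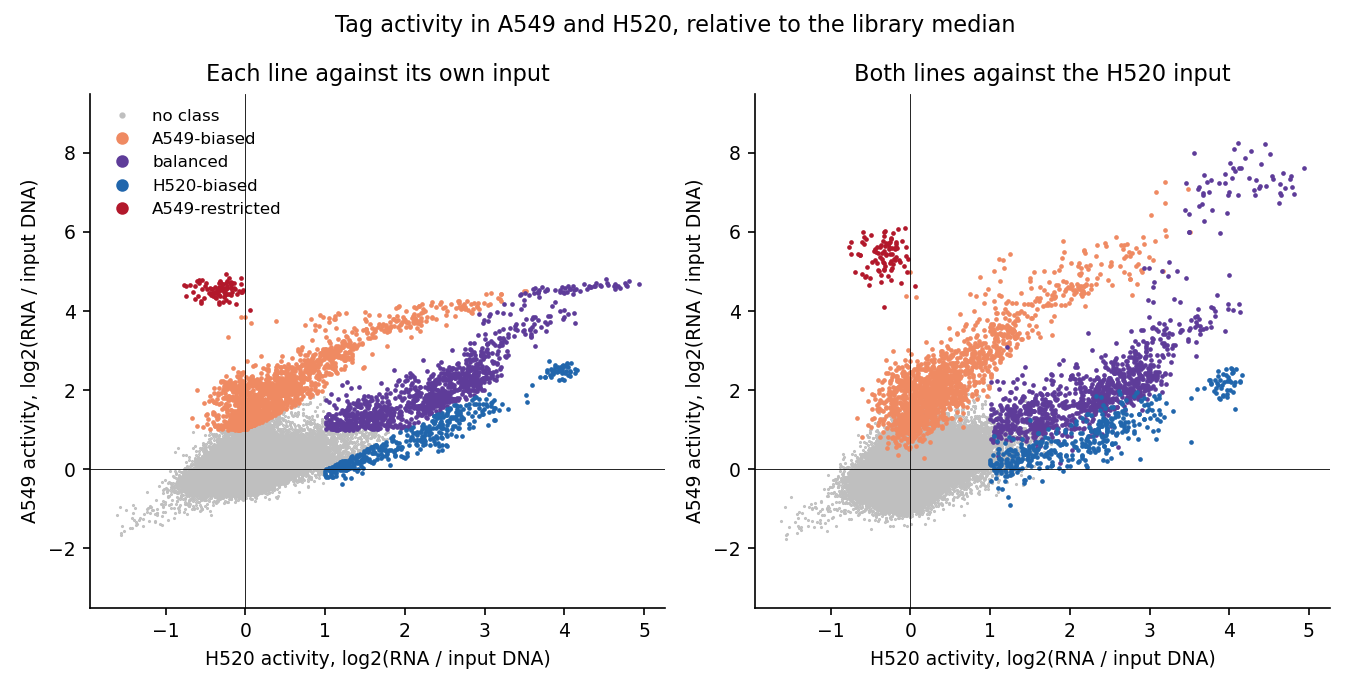
Each point is a tag, placed by its mean log2 activity over 10 RNA libraries of H520 (horizontal) and of A549 (vertical), with each line set against its own input (left) or both lines against the H520 input (right), coloured by class as defined with the own inputs. The 90 A549-restricted tags form a separate group at the upper left, and A549 activity levels off below a log2 value of 5 on the left but not on the right.

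The most active A549 tags by the named rule, ranked against the A549 input, were all A549-restricted: ggagtaatccgcggc at 4.93 ± 0.17 (SD, n = 5), atccggtatcatggc at 4.84 ± 0.19, gcagcgtacgcaggc at 4.83 ± 0.22, gtattgatcggtggc at 4.80 ± 0.17 and gaagagtagctaggc at 4.80 ± 0.19 on the log2 scale with DMSO. In H520 these 5 tags ranged from -0.57 ± 0.10 to -0.08 ± 0.25. The most active H520 tags were classed as balanced. They were tgcgcgtcgaaaggc at 4.99 ± 0.27 (SD, n = 5), gcgcatcgttagggc at 4.86 ± 0.26, cgccgtcgaaagggc at 4.85 ± 0.28, caagccatctacggc at 4.84 ± 0.24 and gttcgcgagtaaggc at 4.82 ± 0.21 in H520 with DMSO. In A549 the same tags had log2 activities of 4.58 to 4.70.

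The values of these strong tags depended on which input library was the denominator, in H520 too: with the mean of both inputs, the 5 named H520 tags read 2.88 to 3.40 there in place of 4.82 to 4.99. Against the A549 input, the highest activity in A549 with DMSO was 30.6-fold and 0 tags exceeded 64-fold. Against the H520 input it was 287-fold and 65 tags exceeded 64-fold. The 5 tags with the highest H520 activity then read 6.89 to 7.55 in A549, above their H520 values, so they were balanced only by the A549 input. The A549-restricted tags named above read 5.71 to 6.11, so the order of these 10 tags turned. The count of active A549 tags was 2380 against the H520 input, and 1998 of the 2179 were among them. Both inputs were then compared in tags with at least 100 counts in each. In the 50 tags with the highest ratio of A549 RNA to the A549 input, a choice that favours tags low in that input, the A549 input held a median of 4.68 times as much as the H520 input.

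**Figure D2:**
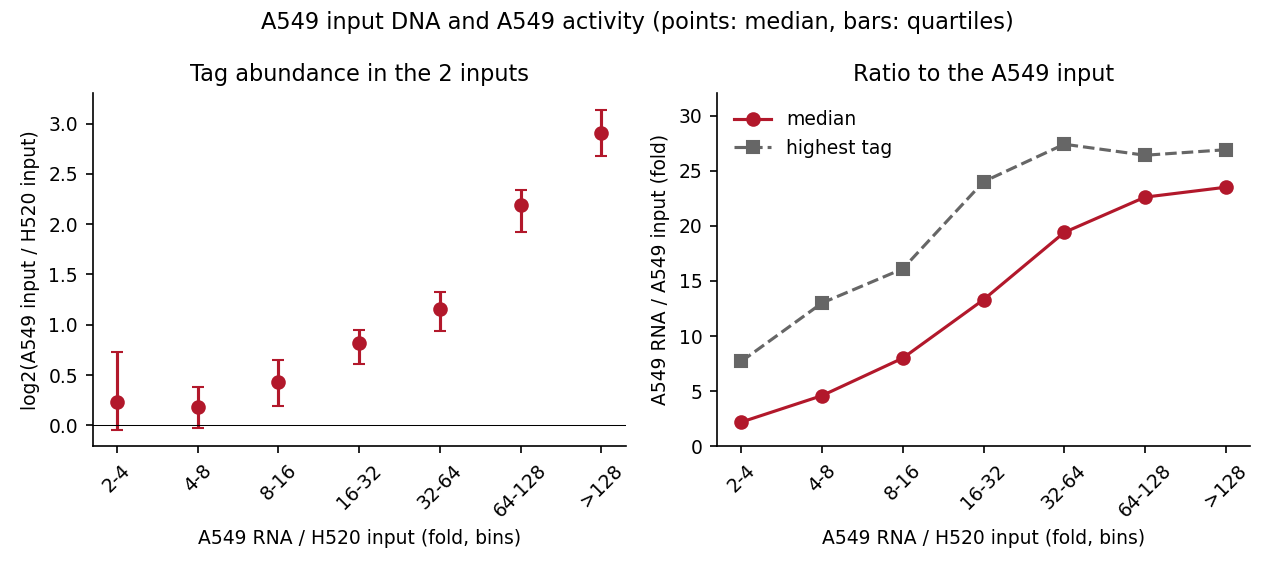
Tags with at least 100 counts in both inputs, binned by the ratio of mean A549 RNA to the H520 input (horizontal, fold). Points give the median log2 ratio of the A549 input to the H520 input with quartile bars (left) and the median and highest ratio of A549 RNA to the A549 input (right). Both axes on the left have the H520 input as denominator, so chance differences in that input add to the slope. The input ratio climbed to 2.91 in the highest bin, while the ratio to the A549 input stayed at or under 27.4.

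The second comparison set A549 against H520 in DMSO, each relative to its own input, to find reporters whose activity differed between an adenocarcinoma and a squamous line. edgeR's glmTreat called 644 tags as more than 2-fold higher in A549 and 490 as more than 2-fold higher in H520, among 222578 tested. Adjusted over the 3167 active tags alone, a set sorted by the same line difference, the counts were 1500 and 374. The A549-higher calls held all 90 A549-restricted tags and 416 A549-biased tags, with median log2 differences of 5.14 and 2.14. The H520-higher calls held 266 H520-biased tags, with a median log2 difference of -1.41, and 1 balanced tag. A further 138 and 223 calls belonged to no class, and their median lower input count was 26 and 33, so these calls rest on few input reads.

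Among calls with at least 500 counts in both inputs, the largest differences toward A549 were tactatgatttgggc with a log2 difference of 5.94 (adjusted p = 4.21e-22), tacttaattggaggc with 5.86 (adjusted p = 3.01e-21) and tagaatcttgctggc with 5.67 (adjusted p = 4.41e-18), by edgeR. All were A549-restricted. By log2 activity against the H520 input in both lines, the first 2 changed places, at 6.44 and 6.48 where their own inputs gave 5.49 and 5.31. The largest toward H520 were gtcagcgtaaggggc at -2.07 (adjusted p = 3.17e-05), gcgttacgaaacggc at -1.95 (adjusted p = 5.72e-11) and gttccgacgaccggc at -1.92 (adjusted p = 1.38e-12), and by log2 activity the last went from -1.91 to -1.34 with the H520 input in both lines. All were H520-biased, with H520 activities of 2.35 ± 0.13 to 3.12 ± 0.14 (SD, n = 5). Without the second A549 DMSO transfection, 1157 tags were higher in A549. Without the input offset the counts were 2013 and 1733.

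The third comparison asked whether BaP changed reporter activity in A549. No change passed the test. edgeR called 0 of 223066 tags, DESeq2 called 0, and 5805 tags (2.60%) had an unadjusted p under 0.05 in edgeR. Without any change, 5% would be expected, so the fit gave fewer small p-values than that. Of the 1602 A549-biased and 90 A549-restricted tags, 0 had such a p. The absence of calls therefore does not exclude a BaP change in these tags. The log2 fold change of BaP over DMSO lay between -0.22 and 0.24 for 95% of tags. The tag with the smallest p, cggacgtttatgggc, had a log2 fold change of 0.59 (SE 0.13, edgeR adjusted p = 1) and went from 0.62 ± 0.05 to 0.93 ± 0.15 TPM (SD, n = 5). By class, A549-biased tags stood at 2.06 ± 0.40 with DMSO and 2.15 ± 0.53 with BaP (exact permutation p = 0.722, n = 5 each, adjusted p = 0.968 over 8 tests). The spread between transfections of that class, 1.57 to 2.51 with DMSO and 1.47 to 2.70 with BaP, was wider than the difference between the treatments. A549-restricted tags stood at 4.54 ± 0.17 and 4.52 ± 0.22 (exact permutation p = 0.833, n = 5 each). Of the 2175 tags active with DMSO, 2101 were also active with BaP.

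**Figure D3:**
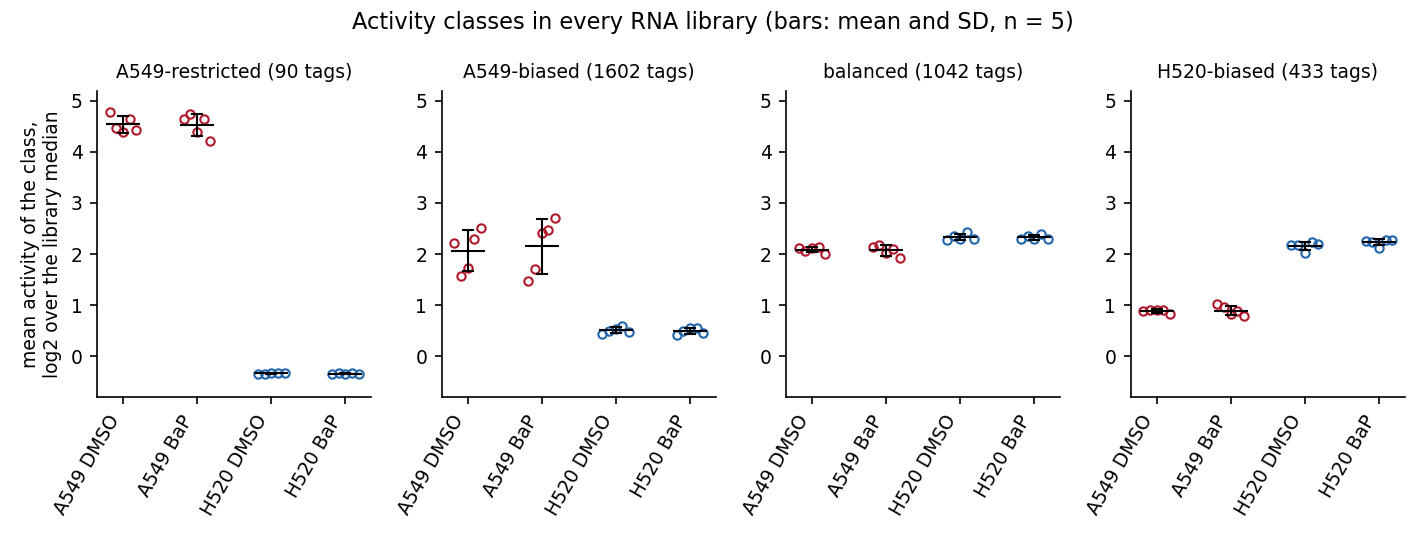
Mean log2 activity of each class in every RNA library (open circles, red for A549 and blue for H520), with the mean and SD of the 5 transfections of each group (bars). The A549-biased class spreads from 1.47 to 2.70 across A549 libraries, while the balanced class stays between 1.92 and 2.18.

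The fourth comparison put the same question in H520. Changes were small here too. edgeR called 0 of 223732 tags, with 10534 (4.71%) at an unadjusted p under 0.05, and DESeq2, which after its own filter adjusted over 19911 of 224276 tags, called 5 higher and 6 lower with BaP. The log2 fold change lay between -0.23 and 0.23 for 95% of tags. The H520-biased tags stood at 2.16 ± 0.08 with DMSO and 2.23 ± 0.06 with BaP, a 1.05-fold difference that did not pass the test (exact permutation p = 0.135, n = 5 each, adjusted p = 0.968 over 8 tests). On the log2 scale the difference was 0.07. Without the third BaP transfection it was 0.101 with an exact permutation p of 0.0159 before adjustment (0.127 after), and without the third DMSO transfection 0.0394 with an exact permutation p of 0.294. These tests left out the transfection number that DMSO and BaP libraries share in their labels. With that number as a block, edgeR called 85 tags higher and 64 lower with BaP. The H520-biased level was higher with BaP in all 5 same-numbered pairs (exact permutation p = 0.0625 within pairs, the smallest possible with 5). The labels do not say whether the numbers mark pairs. Of the 433 H520-biased tags, 367 (84.8%) had a positive log2 fold change, against 110230 of the 220566 tags in no class. A similar share, 1327 of 1602 (82.8%), was positive among A549-biased tags in A549, where no BaP difference passed. Single-tag results were unlike. In H520, 111 of the 433 H520-biased tags had an unadjusted p under 0.05 in edgeR. So did 159 of 1042 balanced tags, 67 of 1601 A549-biased tags and 10194 of the 220566 tags in no class. In A549, 0 of the 1602 A549-biased tags did. Tags are not independent, so these shares have no test of their own. Balanced tags stood at 2.33 ± 0.06 with DMSO and 2.33 ± 0.05 with BaP (exact permutation p = 0.968, n = 5 each).

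Adjusted over the active tags alone, a set chosen after the data were seen, edgeR called 5 tags higher and 2 lower with BaP in H520 and 0 in A549. The 5 that rose were all H520-biased: ttcgtttaccggggc (log2 fold change 0.21, SE 0.045, adjusted p = 0.0275), gtcagcgtaaggggc (0.23), gcgaacgattgcggc (0.23), accttcgtttatggc (0.19) and ctattagttaagggc (0.19). The tags agtaatcccggaggc (-0.19) and ccttgagatcggggc (-0.20), both balanced, fell. The first of these tags went from 41.7 ± 2.72 to 48.2 ± 2.39 TPM (SD, n = 5). These calls were unstable. Leaving out DMSO transfection 1, 2 or 3, or BaP transfection 2 or 5, left 0 calls, and leaving out BaP transfection 4 or 1 left 1 or 4. Leaving out DMSO transfection 4, DMSO transfection 5 or BaP transfection 3 gave 32, 45 or 56 calls. With the transfection number as a block, 323 active tags were higher and 218 lower with BaP.

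The fifth comparison tested whether the lines differed in their response to BaP, with the caveat that exposure times differed. The interaction in edgeR called 0 of 222669 tags, with 7693 at an unadjusted p under 0.05, and DESeq2 called 0. No difference of the class levels passed the test either. For H520-biased tags, BaP minus DMSO was 0.01 in A549 and 0.07 in H520 on the log2 scale (exact permutation of treatment within each line, p = 0.348). For A549-biased tags it was 0.09 and -0.02 (exact permutation p = 0.683). All 4 adjusted p-values were 0.862. These permutations left out the transfection number, and a class test within same-numbered pairs was not run for the interaction. With that number as a block within each line, edgeR's interaction called 0 of 222691 tags.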

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

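The search for single libraries far from the rest of their group was run over 62 groups of 5 values, of which chance alone would mark about 1 in 20, and it marked 3. In H520, the third transfection stood apart on the level of H520-biased tags in both treatments. It was the lowest library with DMSO, at 2.03 where the other DMSO libraries lay between 2.17 and 2.23, and the lowest with BaP, at 2.12 where the others lay between 2.24 and 2.28. The third H520 transfection with BaP also had the largest total, 371.4 M counts, where the other BaP libraries of that line had 200.3 to 230.5 M.

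A signal also appeared in data that no comparison used, and the tests on it were chosen after it was seen. The 4685 tags at 0 in both inputs still received RNA reads, 5.98 per M counts on average over the 20 RNA libraries, with a range of 4.48 to 10.17. The smallest of these library totals had a Wilson 95% interval of 4.24 to 4.74 per M counts, and no single tag of this kind passed 45 counts in a library. Of these tags, 89.9% began with tc.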

How the results depend on the processing

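The alternatives for the allelic, orientation, control-fragment and motif comparisons, and the split of each fragment's tags into 2 sets, were not run, since tags were not tied to fragments. Alternatives for activity centring, denominators and tag GC content, for the line comparison and for class levels were chosen after seeing the data. Among the alternatives that did not leave out a library, 163 values of main results kept their side of the threshold, or stayed within 1.5 times for a count, and 16 did not. A change of sign counted only where either fit had an unadjusted p under 0.05, so some small class differences among the 163 changed sign. For H520-biased tags in A549, BaP minus DMSO was 0.0088 in the main setting and -0.0068 without centring. In A549, BaP calls stayed at 0 in every fit run, and so did the interaction. In H520, DESeq2 gave 11 calls over 19911 tags left by its own filter, where edgeR gave 0. Active-tag calls in H520, 7 in all, fell to 0 at a threshold of 0.01 and to 0 in one fit over all RNA groups, and ranged from 0 to 56 on leaving out a library. For these and the changes below, the cause was not tested.

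By the rule used, which ran over all tags tested in both lines, transfection numbers did not pair DMSO with BaP libraries. Deviations of same-numbered libraries correlated at -0.014 to 0.482 in A549 and 0.042 to 0.151 in H520, with 3 of 5 pairs over 0.1 in A549 and 1 of 5 in H520. As a hint from the data, 9 of 10 H520 libraries but 5 of 10 A549 libraries correlated best with their own number. H520-biased levels of H520 transfections 1 to 5 were 2.17, 2.17, 2.03, 2.23 and 2.20 with DMSO, and 2.25, 2.24, 2.12, 2.28 and 2.27 with BaP. Transfection 3 was lowest and 4 highest in both. A549-biased levels in H520 ranked all 5 transfections alike in both treatments. They were lowest in transfection 1 (0.434 with DMSO and 0.418 with BaP) and highest in 4 (0.587 and 0.552). Balanced levels were highest in transfection 4 in both (2.427 and 2.399), with the lowest in 1 with DMSO and 3 with BaP. A549-restricted levels, below the median in H520, kept no common order, with the lowest in transfection 1 with DMSO and 5 with BaP. The rule therefore does not settle that the H520 libraries were unpaired. With the number as a block, H520 had 149 calls (85 higher and 64 lower with BaP) and 541 among active tags (323 higher and 218 lower). Among the latter, 201 H520-biased tags were higher and 0 lower. Balanced tags gave 117 higher and 163 lower, A549-biased tags 5 and 54, and A549-restricted tags 0 and 1. The level of H520-biased tags in H520 was higher with BaP in all 5 same-numbered pairs (exact permutation p = 0.0625 within pairs, the smallest possible with 5). A549 and the interaction stayed at 0 under the block.

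A549-higher line calls ranged from 492 to 1157 on leaving out a library and were 2013 without the input offset. H520-higher calls ranged from 391 to 567, were 326 with an input minimum of 50, which tests fewer tags, and 1733 without the offset. Without centring, 22 tags in A549 with DMSO and 41 with BaP were more than 2-fold below an RNA to input ratio of 1, in place of the median. Against the other line's input, tags below the median were 13 and 8 in A549 and 97 and 119 in H520. A pseudocount of 1 left 15 and 17 in H520. BaP minus DMSO of H520-biased tags in H520 ranged from 0.0394 to 0.101. Small BaP changes in single tags would often be missed, since the simulated fits called 35.5% (A549) and 55.0% (H520) of the smallest ones tried. Those tags were drawn at random from all tested tags, with independent errors, so these shares do not give the power for active tags.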

Other observations

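All tests in this part were chosen after the result they bear on was seen, except the counts of other splits for the line comparison and for the active tags in A549, which were fixed first. Active tags did not fill the plane of both lines evenly. The 90 A549-restricted tags had a mean log2 activity of 4.53 in A549 and -0.34 in H520, with SDs across tags of 0.17 and 0.18, and 3 tags lay at 3 to 4 in A549 and under 0 in H520. These tags were chosen by a cut at 4, and A549 values against the A549 input level off near it. Against the H520 input their median in A549 was 5.45 with an SD of 0.381. A set of 48 H520-biased tags, chosen by a cut after the data were seen, stood at 3.5 or more in H520, with a mean of 3.92 (SD across tags 0.14) there and 2.45 (SD 0.19) in A549. A further 18 H520-biased tags lay at 3 to 3.5 in H520, with means of 3.10 there and 1.55 in A549. With BaP the 48 tags averaged 3.95 ± 0.14 (SD, n = 5) in H520, against 3.88 ± 0.16 with DMSO.

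The A549 input library held more of the tags that were most active in A549, with a median log2 ratio to the H520 input of 0.94 in 89 A549-restricted tags and -0.01 in tags of no class. The H520 input had a smaller excess of its own. In 49 tags with H520 RNA at 16 to 32 times the A549 input, its median log2 ratio to the A549 input was 0.34 (quartiles 0.22 and 0.57). Both of those ratios have the A549 input as denominator, so chance differences in it add to this excess. The ratio of the restricted tags was 19.5 times its counting error, which argues against low input counts. In tags over 16-fold against the A549 input, the input ratio went with that activity at a Spearman rho of 0.766 in 124 balanced and A549-biased tags, which argues against pools that differ regardless of activity, but at 0.18 in 89 A549-restricted tags (0.35 over all 213), where such pools and other causes cannot be told apart, and the labels name the inputs v1 and v2. A candidate explanation is reads of an A549 RNA library in the A549 input: for the fifth A549 DMSO library, the best fit of 10, the implied share had a median of 2.53% in 343 strong tags, and its class medians of 2.60% (A549-biased), 2.46% (balanced) and 2.51% (A549-restricted) lay 1.06 times apart, against 4.23 times for the first BaP library. Whether such reads entered at the bench or in assigning reads to libraries stays open, a difference of the pools that follows activity was not tested, and no biological explanation was tested, since the input is plasmid DNA.

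The level of A549-biased tags differed between A549 transfections by up to 1.23 log2 units, from 1.47 in the first to 2.70 in the fifth BaP transfection. An even background of plasmid reads would need 70.5% of the lower library and would give a log2 difference of -1.59 in A549-restricted tags, lower minus higher library, but the difference was 0.429. Library depth is open: the level went with the total count at a Pearson r of 0.505 (permutation p = 0.135, adjusted p = 0.203 over 3 relations, Spearman rho 0.564, permutation p = 0.0974, n = 10), and at 0.391 without the 2 farthest libraries. The same tags carried the spread in both treatments, with loadings on the first component of the DMSO and of the BaP transfections correlated at 0.962 across 1602 tags. With BaP the level rose with the labelled transfection number, at 1.468, 1.701, 2.415, 2.471 and 2.697 for 1 to 5. With DMSO it was 2.221, 1.569, 1.723, 2.3 and 2.511, so the first transfection broke that order. An unrecorded batch and a difference in cell state between transfections cannot be told apart, because the labels record neither.

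Tags starting with tc were nearly missing from the plasmid DNA. Of 10766 such tags, 10020 (93.1%, Wilson 95% interval 92.6% to 93.5%) had fewer than 10 counts in both inputs, against 0.87% to 1.81% for the other starting pairs. Tag GC content would not give this, since at least 90.9% of tc-starting tags were under that minimum at each GC content compared and at most 1.90% of other tags were. Loss in amplifying the DNA libraries alone would leave the tags in the RNA, where they took at most 0.0268% of reads. With tc at any later position at most 6.10% of tags were under the minimum, so the loss may come from a sequence formed where the tag joins the vector, such as a cloning site that is no longer cut, which was not tested further because the flanking sequence was not used here.

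Tag GC content went with mean DMSO activity at a Spearman rho across tags of 0.403 in H520 (single libraries 0.294 to 0.435) and 0.107 in A549 (-0.059 to 0.212), with mean BaP activity at 0.393 in H520 (0.267 to 0.443) and 0.149 in A549 (-0.045 to 0.294), and with the ratio of both inputs at -0.006. In H520 with DMSO the median log2 activity was -0.33 for tags with 2 G or C bases of 12 and 0.13 for tags with 10.

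Other groupings of the libraries were tried, on 8000 tags unless said otherwise. Where the real count was 0, every split had to give as many, so for these results the splits decide nothing about chance. This holds for BaP in A549, where all 100 splits counted and the highest other gave 1888 calls, or 2058 among active tags. It also holds for BaP in H520 over all tags, with all 100 splits and a highest other of 286, and for the interaction, with all 40 splits and a highest other of 1. The A549 split with the most calls set DMSO transfections 1, 2 and 3 with BaP transfections 1 and 2 against the rest, which points to a structure of the A549 samples apart from treatment. The 7 active-tag calls in H520 were set against other splits on the full set of tags. Of 40 splits, 13 gave as many or more and the highest other gave 536. Chance cannot be excluded for the fit without a block. The split with the most calls set DMSO transfections 1, 3 and 5 with BaP transfections 3 and 5 against the rest. Except for number 1, it kept same-numbered libraries together, a structure apart from treatment. The splits ignored the transfection number, so they cannot decide about chance if the numbers mark pairs. With the number as a block, 323 active tags were higher and 218 lower with BaP, a fit that these splits do not cover. For the line comparison, the real grouping gave 49 calls and the highest other split 0, so 1 of 60 splits was as large. This argues against a chance division of the libraries alone. Every other split put libraries of both lines on each side, which widens the spread within a side. Each line had 1 input, so the splits cannot tell a difference between the lines from an error in an input.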
